A study of Mus musculus with 2 samples.

How the data were processed

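Open chromatin was profiled by ATAC-seq, in which a transposase inserts adapters into accessible DNA, in 2 groups of C57BL/6 mouse adipose progenitors with 1 library each. Per the labels' protocols, CD137+ and PDGFRα+ cells were isolated by MACS from SAT or VAT, given an adipogenic cocktail and treated with the glucocorticoid dexamethasone at 1 µM. The labels do not say which depot gave which cells. Their extraction text speaks of removing the zona pellucida and washing embryonic cells, which does not match an adipose sample, and markers of early embryo were therefore included among the gene lists. No sample without dexamethasone was analysed here, so no value below measures the effect of the drug.

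Each library has 1 deposited list of peaks that the authors call unique. Per the file headers, a peak carries a chromosome, a start, an end, an Ensembl gene ID and a place class, which is intergenic, intron, exon, up5k or down5k. The lists hold no height, score, p-value or read number, so the depth of each library is unknown and no interval below covers it. CASAVA 1.8 and genome build mm10 are named in the submitters' processing notes, without a role. The aligner, the peak caller, its threshold, any shift of reads for the transposase and the rule that made a peak unique are not given in the sources used here. A deeper library or a looser threshold can lengthen a list of unique peaks, so differences in the number of peaks also carry those settings. Because only unique peaks are listed, a gene without a listed peak may be open in both cell groups or in neither.

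Coordinates are printed as the lists give them, and whether their starts count from 0 or from 1 is not given in the sources used here. Gene positions came from a RefSeq gene table of assembly GRCm38.p6, which is mm10. The match of the builds was tested by position. Of the peaks classed as intron, 95.4% of the CD137 list and 95.2% of the PDGFRα list had their centre in a RefSeq gene, against 41.1% and 41.5% after a shift of 3 Mb. The table pairs no Ensembl IDs with symbols. A peak was therefore given to the protein-coding gene that holds its centre, or else to the nearest one within 5 kb, among 21887 genes. By this rule 7416 CD137 peaks and 4642 PDGFRα peaks lay at a gene. An Ensembl ID was linked to a symbol when at least 80% of its peaks lay at that gene, which linked 6091 of 7163 IDs (85.0%).

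Shares carry Wilson 95% intervals, differences of shares Newcombe intervals, and ratios of peak numbers and CD137 shares at genes exact binomial intervals. All of them cover counting error only. With 1 library per group there is no replicate check, and no p-value is given. Overlap of the lists was counted with bedtools 2.31.1 at a minimum of 1 bp. The number of genes expected in both lists was taken from independent draws and from 1000 draws weighted by gene length. Before the data were examined, 14 gene lists were fixed. For each, the CD137 share of the peaks at its genes was set beside 10000 random gene lists matched on the number of peaks per gene. A list was called outside when at most 2.5% of the random lists had a share as low, or at most 2.5% a share as high, which describes these 2 libraries. Lists with fewer than 5 members with a peak are given as counts. One name, Gilz, was not matched, because it is a synonym of Tsc22d3, which the glucocorticoid list already holds.

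The rule for named genes was also fixed beforehand. It takes Tnfrsf9, Pdgfra, Tead1 and Nr3c1, the 10 genes with the most peaks in each list, the genes of the 5 top-scoring peaks in each list, and up to 4 members of each gene list with the largest difference in peak number. Width stood in for the missing score. The genes with the most peaks were ranked by Ensembl ID among IDs linked to a symbol, and peak counts of other named genes and of the gene lists are by position. The rule was to skip genes known only by clone names or numbers. Some genes that the rule picks are not reported here.

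The steps were tested on simulated data. All of 2000 simulated centres inside a gene were assigned to it. Of unchanged lists of 20 genes, 5.5% were called outside, and 98.5% of lists of 20 genes with 90% CD137 peaks were called high. Only 55% of lists of 7 such genes were called, so a short list can be missed. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

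Alternatives covered the widest peaks of each list, lists of equal length, merging and overlap distances, other assignments of peaks to genes, matching on gene length and counting each gene once. A planned count of 12 sequence motifs, among them the glucocorticoid and TEAD motifs, was not run because no genome sequence was used here. Planned distances to transcription starts were not run because the gene table used here gives no strand. The promoter share was therefore read from the class up5k.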

Results

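Accessible chromatin was compared between 2 populations of adipocyte progenitors that had been differentiated and exposed to dexamethasone. CD137 is the protein of Tnfrsf9 and a marker used for beige progenitors, and PDGFRα is a receptor tyrosine kinase found on stromal progenitors of fat. The series title links glucocorticoids, PDGFRα+ progenitors, white fat and a methylation change at TEAD1, a DNA-binding partner of the Hippo pathway effector YAP. The comparison asked which open sites belong to only one of the populations. Each population was represented by 1 library, without replicates, and by a list of unique peaks without heights or read numbers, so depth is unknown.

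The CD137 list was the longer one, with 14483 unique peaks against 8002 in the PDGFRα list, a ratio of 1.81 (exact 95% interval 1.76 to 1.86). The peaks covered 18703 kb in the CD137 list and 10474 kb in the PDGFRα list. Their widths were close, with a median of 1221 bp (interquartile range 1033 to 1429 bp) in the CD137 list and 1237 bp (1038 to 1455 bp) in the PDGFRα list. No CD137 peak overlapped a PDGFRα peak by 1 bp or more, and 114 CD137 peaks (0.787%) lay within 500 bp of one. The ratio depends on the depth and threshold of both libraries, which are unknown.

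Tnfrsf9, Pdgfra and Tead1, which the study's labels name, and Nr3c1 had few or no unique peaks. Tead1 (chromosome 7, 112679356 to 112906784, mm10) had 2 CD137 peaks and 1 PDGFRα peak, all in introns under ENSMUSG00000055320. The CD137 peaks lay at 112685380 to 112687299 and 112703253 to 112704094, and the PDGFRα peak lay between them at 112699502 to 112700957. A further PDGFRα peak at 112644082 to 112645158, classed intergenic, was 34.7 kb from the gene. Tnfrsf9 (chromosome 4, 150920155 to 150946104), which encodes CD137 itself, had no CD137 peak and 1 PDGFRα peak, at 150927066 to 150928090 in an exon of ENSMUSG00000028965. Within 100 kb it also had 2 CD137 peaks, 26.9 kb away at 150972412 to 150973671 and 82.6 kb away at 150837118 to 150838066, both in introns of other genes. Pdgfra (chromosome 5, 75151322 to 75198206) had no unique peak in either list, and the nearest was a CD137 peak at 75121290 to 75122279, 29.5 kb away and classed intergenic. Nr3c1 (chromosome 18, 39410545 to 39519421), the glucocorticoid receptor gene, also had none, and its nearest was a CD137 peak 21.0 kb away at 39389043 to 39390065. A gene without a unique peak may be open in both populations or in neither, so these counts do not rank its accessibility.

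**Figure D1:**
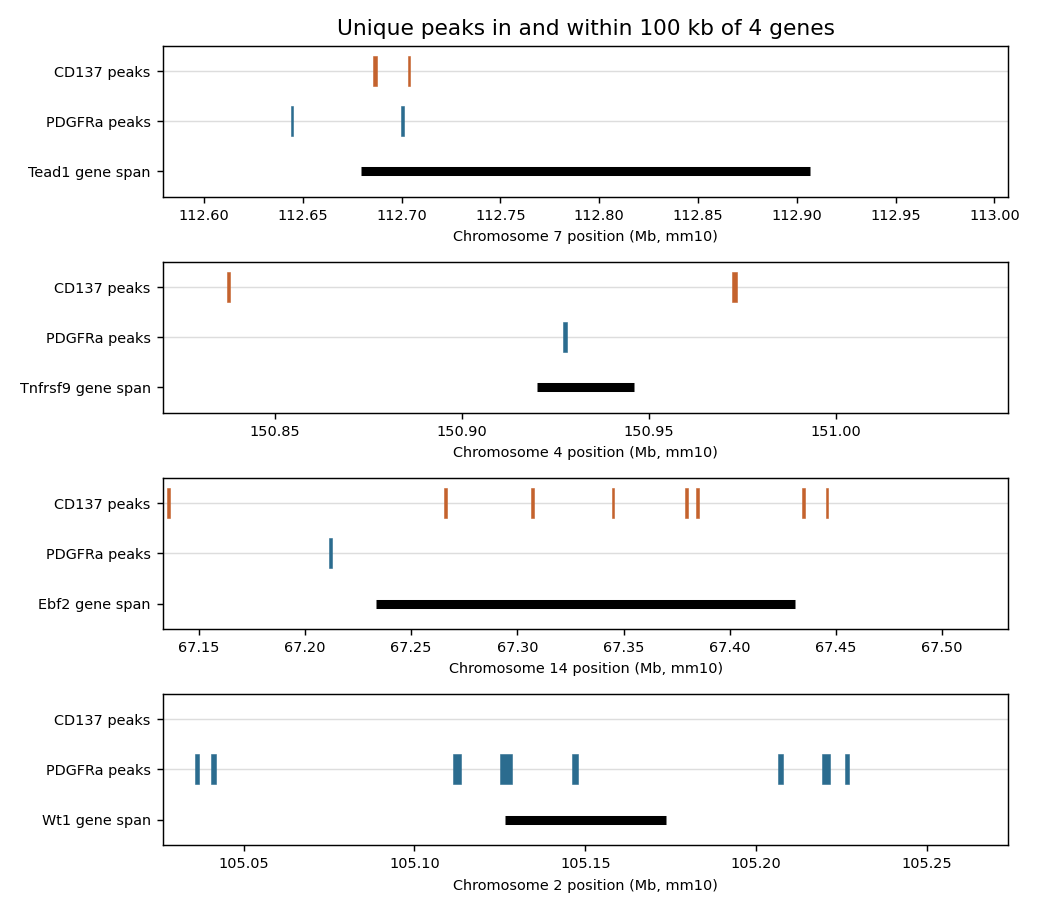
Unique peaks of the CD137 list (orange) and the PDGFRα list (blue) over the spans of Tead1, Tnfrsf9, Ebf2 and Wt1 (black bars) and 100 kb on either side, drawn to scale along each chromosome in Mb (mm10). Ebf2 has 6 CD137 peaks in or within 5 kb of the gene and no PDGFRα peak there, and the Wt1 region has 8 PDGFRα peaks and no CD137 peak.

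The PDGFRα list lay closer to genes than the CD137 list. Intergenic peaks made up 45.3% of the CD137 list and 38.7% of the PDGFRα list, a difference of -6.68 percentage points for PDGFRα minus CD137 (Newcombe 95% interval -8.01 to -5.33). Peaks of the class up5k made up 8.64% and 11.1%, a difference of 2.42 points (1.61 to 3.26), and exonic peaks 7.17% and 9.12%, a difference of 1.96 points (1.21 to 2.72). Introns held 31.7% and 33.6%, a difference of 1.94 points (0.662 to 3.23), whereas the down5k shares of 7.22% and 7.57% differed by 0.358 points, with an interval that includes 0 (-0.350 to 1.08). The median intergenic peak lay 74.2 kb from the nearest gene end in the CD137 list and 48.5 kb in the PDGFRα list. By position, 51.2% of CD137 peaks and 58.0% of PDGFRα peaks were in or within 5 kb of a protein-coding gene, against 46.0% and 48.1% after a shift of 3 Mb. Peaks over a gene end were mostly given the classes up5k or down5k (93.0% of 632 CD137 peaks and 93.3% of 449 PDGFRα peaks), so these classes include the ends of genes. With the 8002 widest CD137 peaks, set against all PDGFRα peaks, the up5k difference was 1.24 points and the intergenic difference -3.36 points. This choice by width favours CD137 up5k peaks (median 1285 bp) over CD137 intergenic peaks (1191 bp). A different measure, centres within 1 kb of either end of a gene, differed by 1.41 points, and within 3 kb by 2.66 points.

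**Figure D2:**
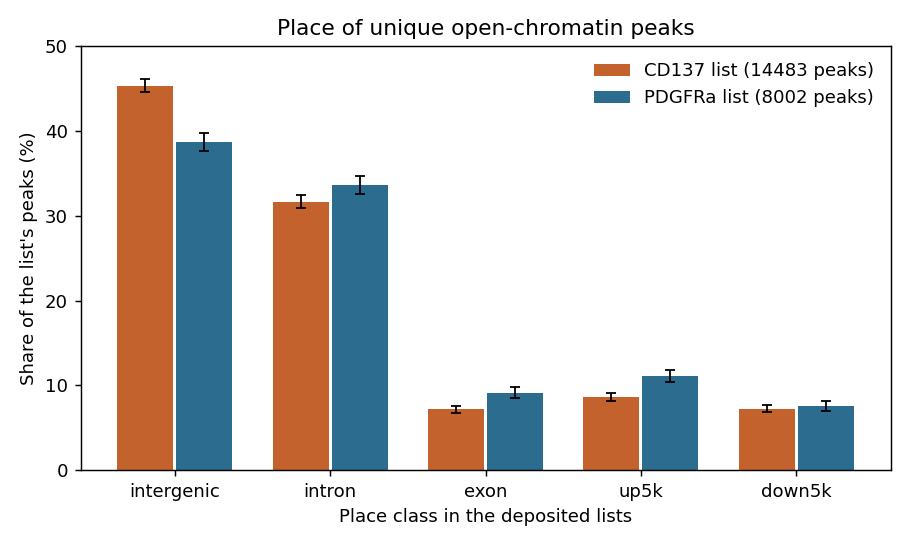
Share of the peaks of each list (vertical axis, percent) in each of the 5 place classes (horizontal axis) for the CD137 list (orange, 14483 peaks) and the PDGFRα list (blue, 8002 peaks), with Wilson 95% intervals that cover counting error only. Intergenic peaks took 45.3% of the CD137 list and 38.7% of the PDGFRα list.

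Genes with several unique peaks more often had peaks of both populations than of 1. The lists held 5027 and 3617 Ensembl IDs, of which 3546 occurred only in the CD137 list, 2136 only in the PDGFRα list and 1481 in both, so that 79.3% of 7163 IDs were in one list. That share is largely set by the 4744 IDs with 1 peak, which can be in one list only. Of the 2419 IDs with 2 or more peaks, 1481 (61.2%) were in both lists, where permuting the list labels over the same peaks gave 1562 on average (1476 to 1636 in 1000 permutations). By position, 4384 and 3326 RefSeq genes had a peak and 1568 had peaks of both lists. Independent lists would share 666 genes, and lists weighted by gene length shared 1489 on average (95% of draws 1441 to 1537), below the number observed. Permuting the list labels over the same peaks gave more shared genes than observed, 1658 on average (1579 to 1732). The first reference redraws the genes of each list, and the second keeps every peak in place, so the observed sharing was above the one and below the other. The CD137 share of peaks was 56.9% (54.4 to 59.4%) at genes below 20 kb, 67.5% (65.8 to 69.3%) above 300 kb and 61.6% over all 12273 pairs of gene and peak.

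Ranked by the peaks under their Ensembl ID, the genes with the most peaks were mostly long genes. The IDs with the most peaks in both lists, ENSMUSG00000092329 (43 CD137 and 24 PDGFRα peaks on chromosome 8 between 120126138 and 124348251) and ENSMUSG00000030849 (22 and 15 on chromosome 7 between 130299004 and 133095173), covered 17 and 9 RefSeq genes and were given no symbol. In each list 3 such unlinked IDs were passed over. In the CD137 list they were Gpc6, a glypican (17 CD137 and 5 PDGFRα peaks), Nav3 (14 and 2), the cAMP phosphodiesterase gene Pde4d (14 and 9), Macrod2 (14 and 3), Anks1b (13 and 2), the cell adhesion gene Opcml (12 and 1), the receptor phosphatase gene Ptprd (11 and 2), Sema5a (10 and 1), Arhgap26 (10 and 9) and Camta1 (10 and 1). All 10 were longer than 300 kb. In the PDGFRα list they were Arhgap26 and Pde4d again, the RNA-binding protein gene Celf4 (1 CD137 and 9 PDGFRα peaks), Kalrn (6 and 8), the potassium channel gene Kcnma1 (3 and 7), the kinesin gene Kif6 (1 and 7), Fry (1 and 7), Ptprg (7 and 7), the nuclear receptor gene Rora (4 and 7) and Ctnnd2 (5 and 7). Of the 10 PDGFRα genes, 8 were longer than 300 kb. Peak counts of the gene lists were taken by position instead, so a gene such as Dlg2, with 14 CD137 peaks by position, can have fewer under its ID.

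Most of the widest peaks had the class up5k. In the CD137 list they were at the immediate early gene Ier2 (7857 bp, chromosome 8, 84658262 to 84666119), the ferritin light chain gene Ftl1 (7144 bp), the glucocorticoid-induced kinase gene Sgk1 (7102 bp, exon, chromosome 10, 21990919 to 21998021), Dlc1 (6673 bp, exon) and the orphan nuclear receptor gene Nr4a1 (6256 bp). In the PDGFRα list they were at Rnase4 and Ang (7776 bp, chromosome 14, 51087915 to 51095691), Tns2 (7431 bp), Zfp503 (7346 bp), Zfp516, a zinc finger activator of Ucp1 (6723 bp), and Hhipl1 (6099 bp). All 5 PDGFRα peaks had the class up5k, as had the CD137 peaks at Ier2, Ftl1 and Nr4a1.

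Among the fixed gene lists, 13 had 5 or more members with a peak, and 1 of them, the DNA methylation machinery, stood outside its random lists, where 0.65 would by chance. Its genes carried 11 CD137 peaks and 1 PDGFRα peak, a CD137 share of 91.7% (exact interval 61.5 to 99.8%), and 2.28% of random lists had a share as high. Of its 19 genes 7 had a peak, 6 of them only in the CD137 list and 1 in both. Mbd2, a reader of methylated CpG, had 3 CD137 peaks, all in introns, at 70578563 to 70579987, 70587395 to 70588485 and 70607653 to 70608532 of chromosome 18. Gadd45a, linked to active demethylation, had 2, the 5-methylcytosine dioxygenase gene Tet3 had 2 and the maintenance methyltransferase gene Dnmt1 had 1, all without a PDGFRα peak. The call rested on few peaks. It was lost when any one of Dnmt1, Tet2, Tet3, Mbd2, Gadd45a or Gadd45b was left out (3.04 to 6.14% of random lists as high), although the CD137 share stayed at 88.9 to 90.9%. It was also lost among the wider 50% of each list (88.9%, with 8.21% as high). Within 50 kb of the genes it held, with 14 CD137 peaks and 1 PDGFRα peak (93.3%, with 0.53% as high). It also held with matching on gene length (1.17% as high) and with the 8002 widest peaks (1.32%). The same was so with each gene counted once (1.83%) and with linked IDs (2.17%). These settings reuse much the same few peaks. With up5k peaks alone the call could not be made. Only 4 members had a peak, under the minimum of 5 (4 CD137 and 0 PDGFRα peaks). The share of 100% was the highest possible, and 10.4% of random lists also reached it.

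Whether the adipocyte list stood apart depended on how its peaks were counted. By peaks it was within its random lists, and by genes it was outside them. The list had 18 CD137 and 15 PDGFRα peaks at 13 of 30 genes, a CD137 share of 54.5% (36.4 to 71.9%), with 17.4% of random lists as low. Pparg, the main transcription factor of fat cell formation, had 3 CD137 peaks and no PDGFRα peak, whereas Mlxipl, a glucose-responsive activator of lipogenesis, had 2 PDGFRα peaks and no CD137 peak. Ebf1 and Rxra each had 5 CD137 and 2 PDGFRα peaks. By genes, 2 adipocyte members were in the CD137 list only, 6 in the PDGFRα list only and 5 in both. With each gene counted once per list, the CD137 share was 38.9% and 2.03% of random lists were as low, which puts it outside.

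The thermogenic and beige list had 23 CD137 and 11 PDGFRα peaks at 12 of 27 genes, a share of 67.6% (49.5 to 82.6%), with 38.5% of random lists as high. Ebf2, a transcription factor of brown and beige precursors (chromosome 14, 67233292 to 67430952), had 6 CD137 peaks and no PDGFRα peak. Esrrg had 5 and 2, Ppargc1a, a coactivator of mitochondrial genes, had 4 and 2, and the potassium channel gene Kcnk3 had 2 and 0. Of the 6 peaks at Ppargc1a, 5 were classed intergenic in the deposited lists, although they lie within the RefSeq span of 662 kb. The white fat regulators had 9 CD137 and 11 PDGFRα peaks at 9 of 20 genes, a share of 45% (23.1 to 68.5%), with 10.8% of random lists as low. Zfp423, a preadipocyte factor that restrains thermogenic genes, had 6 and 2, while Tcf21 and Wt1, transcription factors of mesodermal progenitors, had 0 and 2 each, and Foxc2 had 0 and 1. With each gene counted once per list, the white fat share was 33.3% and 2.08% of random lists were as low, which also puts it outside. Of the 5 white fat members with PDGFRα peaks only, Tcf21, Wt1, Hoxc9 and Hoxc10 are also among the fat depot genes taken up under other observations. The white fat share was not tested without them. With up5k peaks alone, the white fat list had 0 CD137 and 5 PDGFRα peaks, with 1.4% of random lists as low.

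Glucocorticoid response genes had 14 CD137 and 9 PDGFRα peaks at 12 of 29 genes, a share of 60.9% (38.5 to 80.3%) that equalled the median of the random lists. Sgk1 had 4 and 1, the phosphatidylinositol 3-kinase subunit gene Pik3r1 had 3 and 1, the glucocorticoid-induced chaperone gene Fkbp5 had 2 and 1, and Bcl6 had 1 and 0. The Hippo pathway and TEAD list had 23 and 11 at 18 of 30 genes, a share of 67.6% (49.5 to 82.6%), with 32.2% of random lists as high. The upstream Hippo gene Frmd6 had 4 CD137 peaks, the Hippo kinase gene Stk3 had 3 and Wwc1 had 3, with 0, 0 and 1 PDGFRα peaks, and Ptpn14, which binds YAP, had 0 CD137 and 2 PDGFRα peaks. The RNA m6A machinery had 12 and 5 at 8 of 21 genes, a share of 70.6% (44.0 to 89.7%), with 30.9% of random lists as high. The demethylase gene Fto, a gene of 355 kb, gave 7 CD137 peaks and 1 PDGFRα peak, Igf2bp2 gave 2 and 1, and Igf2bp1 and Igf2bp3 gave 1 and 0 each.

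Progenitor and matrix genes had peaks of both lists in similar numbers when counted within 5 kb. Stromal progenitor genes had 10 CD137 and 9 PDGFRα peaks at 15 of 28 genes, a share of 52.6% (28.9 to 75.6%), with 34.6% of random lists as low. Within 50 kb they had 31 and 16 peaks (66.0%, with 35.1% of random lists as high), and with up5k peaks alone 2 and 6 (25%, with 7.36% as low). Of these genes 7 had CD137 peaks only, 7 had PDGFRα peaks only and 1, Fgf10 (2 and 1), had both. The integrin gene Itgb1 had 2 CD137 peaks and Cd34 had 1, and the mesenchymal homeobox gene Prrx1 had 2 PDGFRα peaks, each without a peak in the other list. Extracellular matrix and TGF-beta genes had 20 and 16 at 19 of 31 genes, a share of 55.6% (38.1 to 72.1%), with 33.7% of random lists as low. The elastin gene Eln had 3 and 0, Col6a3 had 2 and 0, the TGF-beta receptor gene Tgfbr2 had 0 and 2, and the fibrillin gene Fbn1 had 3 and 2.

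Endothelial, mesothelial, immune and neuronal markers had peaks in both lists. Endothelial genes had 4 CD137 and 8 PDGFRα peaks at 7 of 18 genes, a share of 33.3% (9.92 to 65.1%), with 5.51% of random lists as low, 1.96% when random lists were matched on gene length, and 35.03% when each gene was counted once per list (4 and 4, 50%). Within 50 kb they had 9 and 11 peaks (45%, with 11.3% as low). The endothelial transcription factor gene Erg had 0 and 3, the VEGF receptor gene Kdr had 0 and 2, Vwf had 1 and 2, and Eng had 1 and 0. Mesothelial genes had 5 and 7 at 8 of 15 genes, a share of 41.7% (15.2 to 72.3%), with 18.5% as low. Gpm6a gave 2 and 0, Wt1 gave 0 and 2, Krt7 gave 0 and 1, and Krt8 gave 1 and 0. Immune genes had 3 and 5 at 8 of 24 genes, a share of 37.5% (8.52 to 75.5%), with 19.5% as low. They included Coro1a, Cx3cr1 and Laptm5 (0 and 1 each). Neuronal genes, kept as a check on gene length, had 58 and 29 at 18 of 22 genes, a share of 66.7% (55.7 to 76.4%), with 31.8% as high. Dlg2 gave 14 and 5, Rbfox1 gave 3 and 9, and Cntnap2 gave 5 and 0. Early embryo markers had 7 CD137 peaks and no PDGFRα peak at 3 of 22 genes, namely Esrrb with 5, Gata4 with 1 and Zp3 with 1. Within 50 kb they had 13 CD137 and 2 PDGFRα peaks at 6 genes (86.7%, with 4.37% of random lists as high).

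**Figure D3:**
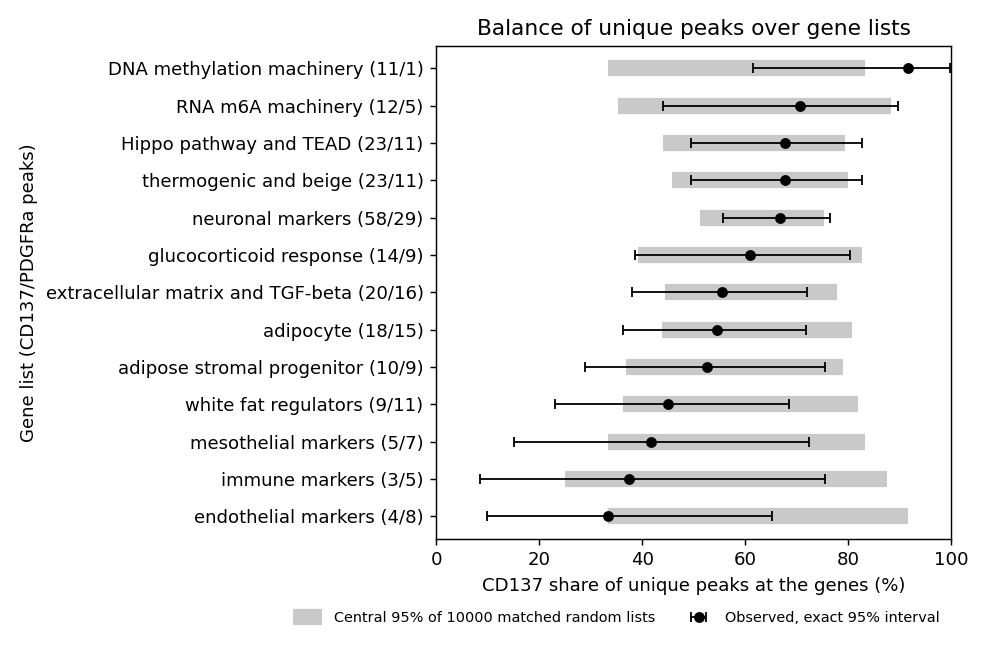
CD137 share of the unique peaks (horizontal axis, percent) at the genes of 13 fixed lists (vertical axis, with CD137 and PDGFRα peak numbers), as points with exact 95% intervals, over grey bars for the central 95% of 10000 random lists matched on peaks per gene. The DNA methylation machinery, at 91.7%, is the 1 list beyond its grey bar, and the others lie within theirs or at the edge.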

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

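The settings with minimum widths, RefSeq genes, a 1 kb or 3 kb distance to gene ends, matched widths, IDs with 2 or more peaks in total, a 50 kb window, linked IDs or up5k peaks alone, and all alternatives for the intergenic share, were chosen after the data were seen. No paired analysis was possible because there is 1 library per group, and for the same reason no library was left out in turn. Depth is unknown and was not equalised.

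The directions of the ratio of peak numbers, of the intergenic difference and of the up5k difference held in all settings run. The ratio was 1.65 for peaks of at least 1500 bp. Within 500 bp of a PDGFRα peak lay 114 CD137 peaks, against 0 that overlapped one. The up5k difference was 3.36 points in the wider 50% of each list and 1.24 with the 8002 widest peaks. A different measure, centres near either end of a RefSeq gene, differed by 1.41 points within 1 kb and 2.66 points within 3 kb. The intergenic difference was -3.36 points with the 8002 widest peaks. That setting drops narrow CD137 peaks only and keeps the whole PDGFRα list. It favours CD137 up5k peaks (median 1285 bp) over CD137 intergenic peaks (1191 bp). The intergenic difference was -6.38 (-7.66 to -4.99) when CD137 peaks were reweighted to the PDGFRα widths, a setting that can move little because the lists have nearly the same widths. The share of genes in one list was 84.4% in the wider 50%, 80.7% with the 8002 widest peaks, 82.0% when an ID needed 2 or more peaks in a list to count as in it, 38.8% for IDs with 2 or more peaks over both lists together, and 74.5% by RefSeq position. IDs with 1 peak can be in one list only, which by construction raises the share over all IDs. The number of gene lists outside their random lists was 1 in the main setting, 2 with matching on gene length (endothelial added), 0 in the wider 50% and 3 with each gene counted once (adipocyte and white fat added). With up5k peaks alone it was 1, the white fat list (1.4% as low). In that setting DNA methylation, with 4 members with a peak, could not be called. Its share of 100% was also reached by 10.4% of random lists. For these moves the cause was not tested. Of 89 further list shares under other settings, 78 stayed within the exact interval of the main share and 11 left it. Staying within says little, because the settings reuse the same peaks and the intervals are wide, such as 8.52 to 75.5% for immune genes. The adipocyte share of 38.9%, with each gene counted once, was within its interval although outside its random lists.

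Not run were the motif shares, the distances to transcription starts, and gene lists from peaks near transcription starts, for want of sequence and strand. The ratio of peak numbers in the widest 50% or in equal lists is fixed by construction and was also left out.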

Other observations

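The depot lists, the pair distances and the ribosomal genes were set before their results were seen. The mesothelial and the spacing tests, the threshold of 8 peaks and the genes named in the next 2 paragraphs were chosen after.

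Some genes collected many peaks of one list and none of the other. With 5 or more peaks, 42 genes had CD137 peaks only, where permuted list labels gave 23.3 on average and at most 42 in 1000 permutations. Among them were Fhit and Ntm with 9 peaks each, Creb5 with 8, the axon guidance receptor gene Robo1 with 7, Ebf2 with 6, and Angpt1, a ligand of the endothelial receptor Tek, the transcription factor gene Ets1 and the growth hormone receptor gene Ghr with 5 each. The reverse held for 9 genes, against 1.89 on average and at most 9 by permutation, among them the integrin gene Itga1 and Kcnab1 with 6 peaks each, and the calcium channel gene Cacna1d, the muscarinic receptor gene Chrm3, Epb41l2 and Nlgn1 with 5 each. Genes with peaks of both lists numbered 1568, fewer than in any permutation of the list labels over the same peaks (1579 to 1732).

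Within 100 kb of a gene, 13 of 21330 protein-coding genes shorter than 300 kb had 8 or more CD137 peaks and no PDGFRα peak, among them Tbx15 and its neighbour Wars2, Angpt1, Ptn and Zfp608. Wt1 was the 1 gene with the reverse, with 8 PDGFRα peaks and no CD137 peak. Its peaks included a 3551 bp peak of the class up5k at 105125051 to 105128602 of chromosome 2 and an intronic peak at 105146208 to 105147981. At Tbx15 the CD137 peaks included 99239713 to 99242226 (up5k) and 99245846 to 99248399 (intron) of chromosome 3. No number from permuted list labels is given for the threshold of 8 peaks. The CD137 list held 64.4% of all peaks, and neighbours such as Tbx15 and Wars2 share peaks. The contrast of 13 genes with 1 is therefore a description only.

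Tbx15 is a known marker of subcutaneous fat and Wt1 of visceral fat, and the labels leave the depot of each population open, so a difference of depot was weighed as a candidate explanation. In lists of 11 depot genes each, the subcutaneous genes had 10 CD137 and 3 PDGFRα peaks (76.9%) and the visceral genes 2 and 4 (33.3%). Tbx15 itself gave 4 of these CD137 peaks and Wt1 2 of these PDGFRα peaks. The lists are therefore not independent of the 2 genes that raised the question. Other members went the opposite way. Hoxa9, Hoxc9 and Hoxc10 of the subcutaneous list had 0 CD137 peaks and 1 PDGFRα peak each, and Gata4 and Tbx5 of the visceral list had 1 and 0. The difference of 43.6 points was matched or exceeded by 6.4% of random list pairs, and only 4 visceral genes had a peak, under the minimum of 5, so depot and cell population cannot be told apart. Mesothelial cells also use Wt1, and their presence among the PDGFRα cells stays open as well. Of random lists, 18.5% had a CD137 share as low as the mesothelial list. Krt7, Lrrn4 and Rspo1 had 0 CD137 peaks and 1 PDGFRα peak each, whereas Gpm6a had 2 and 0 and Krt8 had 1 and 0. Msln, Upk3b, Krt18 and Krt19 had no unique peak, which decides nothing, as they may be open in both populations or in neither. Sorting on PDGFRα should leave mesothelial cells out as far as they lack the receptor. Wt1 and Bnc1 stand in both the mesothelial and the visceral list, and a difference between CD137+ and PDGFRα+ cells themselves was not tested.

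Peaks of one list lay near each other. Of pairs 5 to 20 kb apart 59.1% were from the same list and of pairs 20 to 100 kb apart 56.4%, above the highest of 100 permutations (56.1% and 55.2%), which argues against wide open regions split into several peaks as the whole cause. A difference over stretches of 1 to 3 Mb, such as in copy number, is also argued against as the general cause. The excess at 1 to 3 Mb was -0.0488 points, against 2.16 at 20 to 100 kb. This pooled excess does not speak to a difference of a single whole chromosome. The CD137 share was 58.4% on chromosome 17, against 64.4% over all chromosomes. Below 5 kb the same-list share was 32.0%, under the permuted 54.4%. The test of a minimum spacing, set when peaks were called or merged, gave mixed results. In the CD137 list, pairs 3 to 5 kb apart were 0.449 times (0.363 to 0.553) as many as pairs 5 to 7 kb apart. The ratio was 0.316 (0.211 to 0.463) in the PDGFRα list and 1.34 (1.15 to 1.57) across lists, as such a spacing predicts. A strict minimum forbids gaps under 1 kb, yet 79 CD137 and 32 PDGFRα neighbours had one, down to 4 and 7 bp. A strict minimum is therefore argued against, but a looser spacing rule is not, and what set this dearth stays open. No biological explanation was tested.

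Wide peaks stood in the CD137 list at Ier2 and Ftl1, genes used in most cells, which raises whether a unique peak may still be open in the other population. Ribosomal protein genes, open in every cell, had a peak of either list within 1 kb of an end in 2 of 77 cases (2.60%, 0.715 to 8.98%), against 4.93% of 11771 other protein-coding genes below 20 kb. The interval includes the share of the other genes, so the 2 readings of a unique peak cannot be told apart by this test, which has too few genes. No biological explanation was tested.

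The CD137 share of peaks was lowest on chromosome 17 among chromosomes 1 to 19 and X (58.4%, 55.2 to 61.5%), and below that of the other chromosomes in each of the 5 place classes, although for intron, exon and up5k peaks the interval included the share of the other chromosomes. Chromosome Y held 2 CD137 and 4 PDGFRα peaks.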
